A study of Mus musculus with 18 samples.

How the data were processed

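The series holds 18 Affymetrix whole-genome mouse expression arrays, each hybridized with liver RNA of a single female mouse. There were 6 groups of 3 animals, and each array was assigned to its group from the sample labels. Per the labels, liver was minced in a preservative and stored frozen, RNA was isolated with Trizol and RNeasy, and 10 ug of RNA was biotin labelled. The deposited table gives log2 signals that the authors computed from the scanned arrays, and their background correction, normalization and summary method are not given in the sources used here. That the values are log2 was checked against their range. No detection calls were used here, and a group mean under the lowest array median was taken as not shown to be above background, a bound chosen after the data had been seen. Array medians lay between 4.25 and 4.35 and correlations between arrays between 0.979 and 0.995. Signal over background, not read depth, limits what can be measured for dim probe sets, and 3 animals per group limit the precision.

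Of the probe sets, 64 are controls, 34945 map to 1 gene in the platform annotation, 932 to several and 9160 to none. Symbols of 34754 probe sets were updated through Entrez identifiers to current mouse gene names. A probe set was kept if its signal was above the median of its array in at least 3 of the 18 arrays, which left 24396, of which 20712 carry 1 gene. The probe set with the highest mean stood for its gene, which gave 12169 genes.

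A linear model with a mean for each of the 6 groups was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend and 12 residual degrees of freedom. The 7 contrasts were each of the 4 chemicals against its own control, corn oil against feed control, 1,5-naphthalenediamine against N-(1-naphthyl)ethylenediamine, and the mean effect of the positive liver carcinogens against that of the negative chemicals. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Errors of gene changes are standard errors of the model, and errors of array measures are standard deviations. For the 4 chemicals, changes of genes are given relative to the median change of all tested genes. Genes with arrays that do not overlap between the groups compared were counted as well.

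Groups of genes were tested with camera in limma with a preset correlation of 0.01 between genes. The estimated correlation of each list and the rotation test fry were alternatives. There were 34 lists, covering xenobiotic and stress responses, metabolism, sex-biased and zonal liver genes and markers of other cell types, and 31 had at least 5 tested members. Members were also adjusted over their list alone. Matching of listed symbols was corrected after list results had been seen, because 4 symbols in 4 lists had been matched as aliases of other genes. The values given are those after the correction.

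The genes named follow a rule: the 8 largest rises and the 8 largest falls among called genes without overlap, the 3 members with the largest t statistic from each called list, and up to 3 members of lists that did not pass. From these, genes were chosen for the text after their values were seen, mostly those that keep their call when any 1 array is left out.

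The groups, contrasts, lists, filter, thresholds and rule for named genes, and most alternatives, were fixed before the data were examined. Alternatives included quantile normalization, centring, other filters, other probe sets per gene, array weights, RNA integrity as a covariate, pooled controls, stricter thresholds and leaving out each array in turn. Those added after the data had been seen were the beta-actin 3' minus 5' signal and an index of clock genes as covariates, leaving out 5 arrays with high 18S ribosomal RNA signal, centring on the median of the tested genes, corn oil controls for the second chemical of a pair that shares feed controls, and the first matching of listed symbols. Overlaps of calls were compared with the product of the list sizes and with 50 simulated sets of unchanged groups that share a control group. These groups, the control included, were drawn at random from the residuals of all 18 arrays, with random signs. The procedure was tested on simulated data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.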

Results

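Liver RNA was profiled in 18 female B6C3F1 mice, a hybrid strain used in rodent cancer bioassays, in 6 groups of 3 animals. Per the labels, the mice were 5 weeks old at the start and were exposed for 13 weeks to 1 of 4 chemicals or to a control. The labels class 1,5-naphthalenediamine (2000 ppm in feed) and 2,3-benzofuran (240 mg/kg by gavage in corn oil, 5 days per week) as positive liver carcinogens. N-(1-naphthyl)ethylenediamine, given as its dihydrochloride (2000 ppm in feed), and pentachloronitrobenzene, a fungicide (8187 ppm in feed), are classed as negative. The 3 feed chemicals shared a feed control, and 2,3-benzofuran had a corn oil gavage control. The series title names the purpose, which is to find expression markers for liver tumours in long-term rodent bioassays. Each array gave log2 signals for its probe sets, and 12169 genes were tested. With 3 arrays per group, the number of arrays limits the precision.

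The arrays of the controls differed from those of the exposed animals in the upper part of the signal distribution. Medians over all probe sets lay between 4.31 and 4.35 in the 6 control arrays and between 4.25 and 4.32 in the 12 treated arrays, whereas 75th percentiles lay between 6.10 and 6.26 in controls and between 6.32 and 6.41 in treated arrays. As a result, the median log2 change of all tested genes was 0.175 for 1,5-naphthalenediamine, 0.109 for 2,3-benzofuran, 0.155 for N-(1-naphthyl)ethylenediamine and 0.148 for pentachloronitrobenzene, against 0.0387 between the control groups. Changes of genes under the 4 chemicals are therefore given below relative to that median, while calls and counts use the deposited scale. The median change also depended on signal level. In genes with a mean under 5 it was -0.113, -0.0949, -0.0452 and -0.0983 for the 4 chemicals in the same order. Between 7 and 8 it was 0.318, 0.25, 0.267 and 0.237. Lists of dim genes can therefore lie lower than the median through this alone, and lists of genes with means between 6 and 12 higher. The list tests below did not match genes by level. Group means below the lowest array median, 4.25, are not shown to lie above background, since Y-linked probe sets reached 3.54 in these female animals. Rises from such means are given as at least the size printed. For falls to such means the bound is the change on the deposited scale, not the larger one relative to the median. RNA integrity numbers in the labels ranged from 7.4 to 9.4. The lowest group mean, 7.83 ± 0.231 (SD, n = 3), was that of N-(1-naphthyl)ethylenediamine, against 8.9 ± 0.173 in the feed control.

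**Figure D1:**
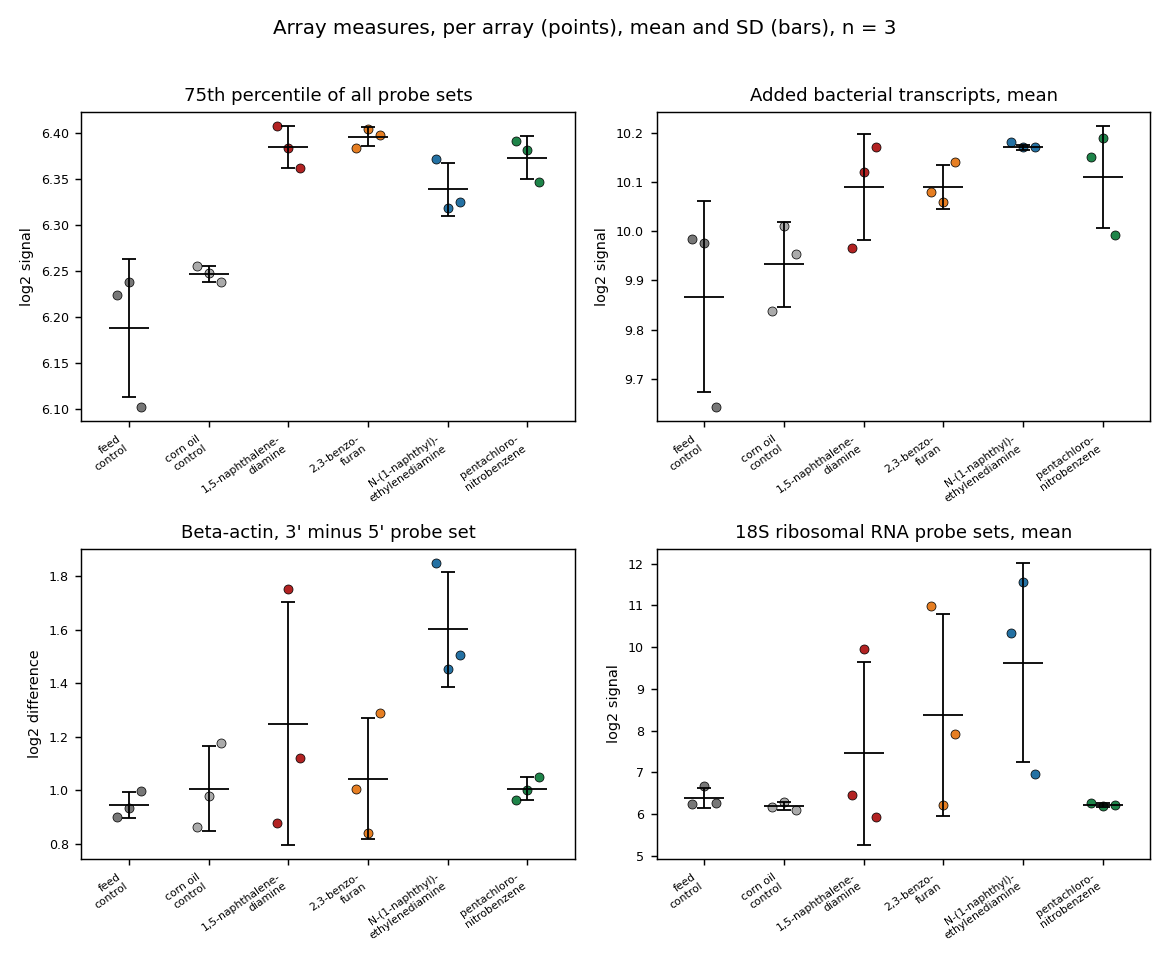
Array measures in log2 units for the 6 groups on the horizontal axes: the 75th percentile of all probe sets, the mean of bacterial transcripts added before hybridization, the beta-actin 3' minus 5' difference and the mean of the 18S ribosomal RNA probe sets; points are arrays, horizontal bars are means and error bars are SD (n = 3). The 6 control arrays lie between 6.10 and 6.26 in the 75th percentile and the 12 treated arrays between 6.32 and 6.41.

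The first comparison asked which liver genes 1,5-naphthalenediamine changed against the feed control. Abcc4, an efflux transporter, rose at least 14.1-fold (log2 change 3.82 ± 0.287, SE, n = 3 per group; limma adjusted p = 6.13e-08), from a mean log2 signal of 3.90 in feed controls to 7.90. 9130409I23Rik rose by 3.41 ± 0.254 and the long non-coding RNA host gene Snhg11 by at least 3.37 ± 0.311. The glutathione S-transferases Gsta2 and Gstm3 rose by 3.23 ± 0.356 and 3.06 ± 0.255 on the log2 scale, and Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, by at least 3.05 ± 0.291. Cd36, a fatty acid transporter, and Lpl, lipoprotein lipase, rose by 3.06 ± 0.306 and 2.38 ± 0.307. Slco1a1, an organic anion transporter, fell 19.5-fold (log2 change -4.29 ± 0.59, adjusted p = 0.000109). Gprin3 fell as well, at -3.08 ± 0.532, as did Serpina12 at -2.47 ± 0.377 and the steroid dehydrogenase gene Hsd3b5 at -2.62 ± 0.444. The mean of Hsd3b5 went from 6.10 to 3.66, under the lowest array median, so its change on the deposited scale was -2.44 or stronger. In each of these genes all 3 treated arrays lay on one side of all 3 controls, which was a condition for being named.

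Targets of NRF2, the transcription factor of the oxidant response, rose as a group with 1,5-naphthalenediamine. Of 26 measured targets 23 rose and 3 did not pass, or 23 up and 1 down adjusted over the list alone, with Ugdh at 2.19 ± 0.143, Gstm1 at 1.20 ± 0.0971 and Gstp1 at 1.12 ± 0.0852 (camera adjusted p = 3.02e-12; adjusted p = 0.258 with an estimated correlation). Among 19 glutathione S-transferases 17 rose, and 18 adjusted over the list alone, led by Gstm2 at 1.84 ± 0.105 (camera adjusted p = 1e-08; adjusted p = 0.283 with an estimated correlation). Aryl hydrocarbon receptor targets rose in 4 of 5 cases, also when adjusted over the list alone, with Cyp1a2 at 1.39 ± 0.126 (camera adjusted p = 0.000156; adjusted p = 0.258 with an estimated correlation). Among these 5, Ugdh and Nqo1 are also in the NRF2 list, so the 2 lists are not independent. Cholesterol synthesis genes rose in 13 of 20 cases, and in 14 adjusted over the list alone, with Sqle, squalene epoxidase, at 1.25 ± 0.216 and Cyp51 at 0.90 ± 0.156 (camera adjusted p = 0.00134; adjusted p = 0.552 with an estimated correlation). The glutathione S-transferase, aryl hydrocarbon receptor and cholesterol synthesis lists were also called higher in the corn oil control. That control had no chemical and was set against the same feed control, as given below. In the mitochondrial respiratory chain 16 of 19 genes rose, 18 adjusted over the list alone and 6 after quantile normalization, with a median of 0.0739 (camera adjusted p = 0.00403; adjusted p = 0.604 with an estimated correlation). Its members Ndufa4, Sdha and Ndufs1 had feed control means of 11.51, 11.03 and 9.41. On the deposited scale the median change of all genes was 0.247 at means between 9 and 10 and 0.205 between 10 and 12. Over all levels it was 0.175, so this call can come in part from signal level.

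Cell cycle genes lay lower with 1,5-naphthalenediamine (camera adjusted p = 0.00755; adjusted p = 0.258 with an estimated correlation). Ccnd1, cyclin D1, and Ccne1, cyclin E1, fell by 1.59 ± 0.217 and 1.00 ± 0.123, and the other 18 of 20 did not pass, with the same counts adjusted over the list alone. Macrophage and Kupffer cell markers had a median of -0.38, with 3 of 20 lower, 1 higher and 16 not passing, 1 of each adjusted over the list alone, and 11 lower after quantile normalization (camera adjusted p = 0.00275; adjusted p = 0.552 with an estimated correlation). Stellate cell and lymphocyte lists also lay lower. In the former 1 of 17 rose and 1 fell, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.0157; adjusted p = 0.549 with an estimated correlation), and the call was lost without feed control 28 (adjusted p = 0.0667). In the latter 2 of 12 rose and 2 fell, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.0293; adjusted p = 0.283 with an estimated correlation), and the call was lost without feed control 28 or treated animal 4 (adjusted p up to 0.107). The interferon response list had a median of -0.295, with Cxcl9 at -1.34 ± 0.164, 5 of 20 members lower, 1 higher and 14 not passing, and 4 and 1 adjusted over the list alone (camera adjusted p = 0.00438; adjusted p = 0.552 with an estimated correlation). The interferon call was lost without feed control 27 (adjusted p = 0.0509). Targets of p53 did not pass as a list, although 8 of 18 rose, or 9 up and 1 down adjusted over the list alone (camera adjusted p = 0.0807).

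In all, 4859 of 12169 genes passed with 1,5-naphthalenediamine, 3836 higher and 1023 lower. After quantile normalization 1483 were higher and 1478 lower, and with arrays centred on the median of the tested genes 1122 were higher and 3025 lower, so the split between directions follows the scaling. The treated and control arrays did not overlap in 5662 genes, where chance gives 10%, and in 4441 of the called genes. Both counts are on the deposited scale, where the shift between treated and control arrays alone can separate genes. The 10% does not account for that shift. Treated animal 4 had 18S ribosomal RNA signal of 9.97 and a beta-actin 3' minus 5' difference of 1.75, against 5.94 to 6.47 and 0.875 to 1.12 in the other 2 treated arrays. Without the 5 arrays with the highest 18S signal in the series the count was 2772.

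**Figure D2:**
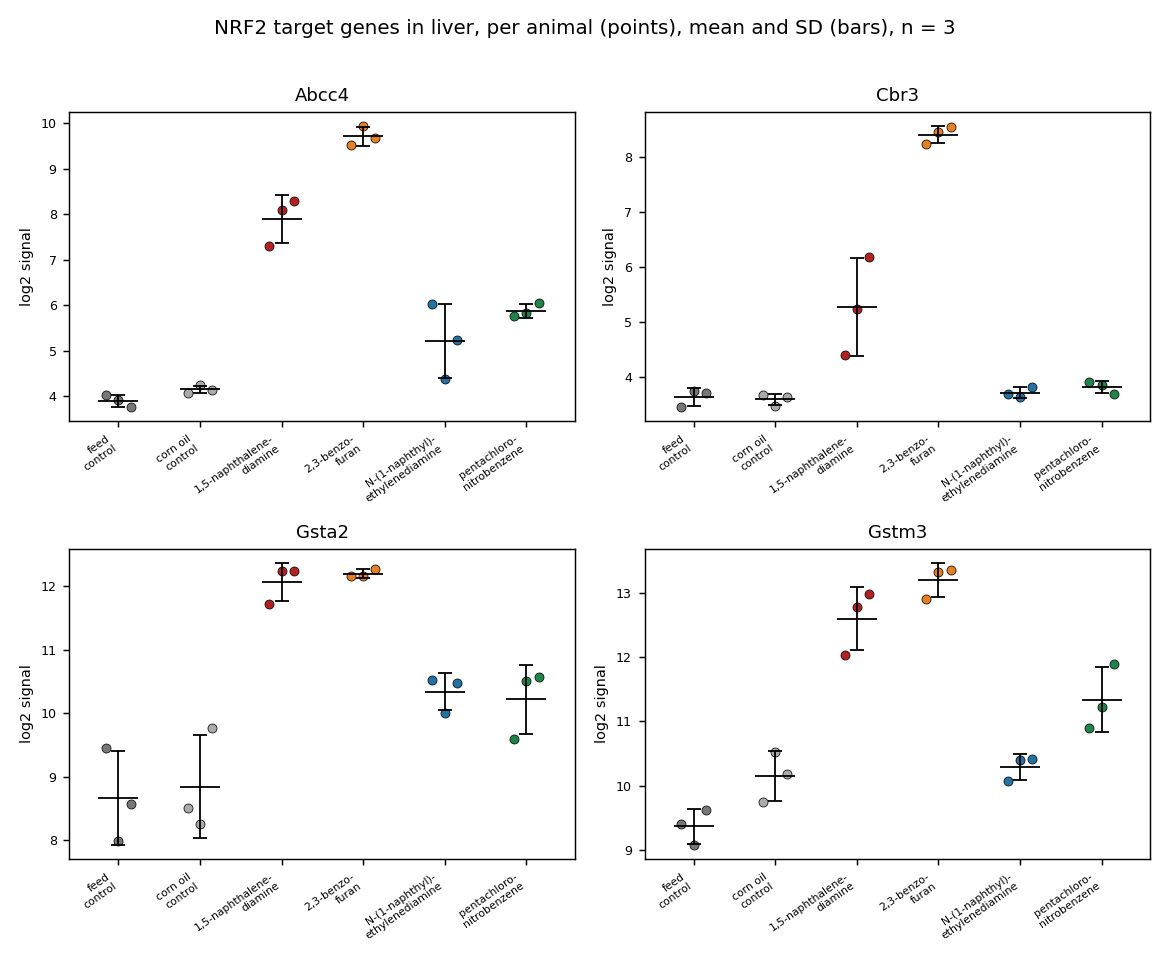
Log2 signal of Abcc4, Cbr3, Gsta2 and Gstm3 on the vertical axes in the 6 groups; points are animals, horizontal bars are means and error bars are SD (n = 3). Mean Abcc4 signal was 3.90 in feed controls, 4.16 in corn oil controls, 7.90 with 1,5-naphthalenediamine and 9.71 with 2,3-benzofuran.

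The comparison of 2,3-benzofuran with the corn oil control asked the same of the other carcinogen. Abcc4 rose at least 43.6-fold (log2 change 5.45 ± 0.287, SE, n = 3 per group; limma adjusted p = 3.55e-10), Cbr3, a carbonyl reductase, by at least 4.71 ± 0.265 and Cyp4a12a, a male-biased cytochrome P450, by at least 4.48 ± 0.166. Tfrc, the transferrin receptor, rose by 3.27 ± 0.328, Gsta2 by 3.25 ± 0.356 and Asns, asparagine synthetase, by 3.21 ± 0.158. Among the falls were Slco1a1 at -3.29 ± 0.59, Hao2, a hydroxyacid oxidase, at -3.05 ± 0.477 (adjusted p = 0.00027), Sult2a2, a sulfotransferase, at -3.67 ± 0.847 (adjusted p = 0.00447) and Cyp3a44 at -2.12 ± 0.274. All 3 treated arrays lay on one side of all 3 controls for each of these genes, again a condition for being named.

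NRF2 targets rose in 24 of 26 cases with 2,3-benzofuran, the same number adjusted over the list alone, including Nqo1, a quinone reductase, at 2.49 ± 0.228 and Gstp1 at 1.30 ± 0.0852 (camera adjusted p = 1e-18; adjusted p = 0.122 with an estimated correlation). Of 19 glutathione S-transferases 11 rose, also adjusted over the list alone, with Gstm2 at 1.45 ± 0.105; after quantile normalization 9 rose and 3 fell (camera adjusted p = 0.000621; adjusted p = 0.37 with an estimated correlation). Ribosomal protein genes rose in 9 of 11 cases, and in 10 adjusted over the list alone, with Rplp0 at 0.36 ± 0.0898 (camera adjusted p = 0.00819; adjusted p = 0.438 with an estimated correlation).

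Several liver and immune lists lay lower with 2,3-benzofuran. Acute phase genes fell in 11 of 24 cases and rose in 1, also adjusted over the list alone, with Lbp, the lipopolysaccharide binding protein, at -1.08 ± 0.134 and Saa4 at -0.72 ± 0.108, while Orm3 rose by 1.48 ± 0.248 (camera adjusted p = 2.69e-06; adjusted p = 0.298 with an estimated correlation). Interferon response genes fell in 9 of 20 cases and rose in 1, or 10 and 1 adjusted over the list alone, with Cxcl9 at -1.41 ± 0.164 and Ifit3 at -1.06 ± 0.157 (camera adjusted p = 2.69e-06; adjusted p = 0.249 with an estimated correlation). Macrophage and Kupffer cell markers fell in 6 of 20 cases, with Mpeg1 at -0.81 ± 0.133 and Csf1r at -0.67 ± 0.145, and 1, Cd14, rose by 0.90 ± 0.142, the same counts adjusted over the list alone (camera adjusted p = 0.000224; adjusted p = 0.37 with an estimated correlation). Lymphocyte markers fell in 2 of 12 cases, also adjusted over the list alone, with Gzma at -0.65 ± 0.128 (camera adjusted p = 0.00819; adjusted p = 0.249 with an estimated correlation). Endothelial markers fell in 3 of 15 cases and in 0 adjusted over the list alone, with Stab2 at -0.69 ± 0.178 (camera adjusted p = 0.00819; adjusted p = 0.385 with an estimated correlation). The call of Stab2 was lost without treated animal 6 or corn oil control 24 (adjusted p up to 0.077), and those of the other 2, Ptprb and Fcgr2b, without 4 and 5 of the 6 arrays (adjusted p up to 0.181 and 0.141). Stellate cell and matrix genes fell in 2 of 17 cases and rose in 1, also adjusted over the list alone, with Reln at -0.56 ± 0.119 (camera adjusted p = 0.00819; adjusted p = 0.298 with an estimated correlation). Neutrophil markers lay lower with 0 of 6 passing in limma, also adjusted over the list alone, and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0116; adjusted p = 0.249 with an estimated correlation). Female-biased liver genes fell in 5 of 12 cases, or 6 adjusted over the list alone, with Hao2 and Cyp3a44 as given above and Prom1 at -2.17 ± 0.517 (camera adjusted p = 0.000128; adjusted p = 0.249 with an estimated correlation). Of 13 male-biased genes 7 rose and 3 fell, also adjusted over the list alone, with Cyp2d9 at 2.86 ± 0.228, but that list did not pass (camera adjusted p = 0.174). Cholesterol synthesis genes fell in 4 of 20 cases, also adjusted over the list alone, with Tm7sf2 at -0.62 ± 0.104 (camera adjusted p = 0.000377; adjusted p = 0.37 with an estimated correlation). The falls in this paragraph were measured against the corn oil control. It lay higher than the feed control in the cholesterol synthesis, interferon response, macrophage and female-biased lists, as given below.

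In total 3936 genes passed with 2,3-benzofuran, 3013 higher and 923 lower, against 1537 and 1305 after quantile normalization and 1367 and 2619 with arrays centred on the median of the tested genes. Treated animals 6 and 10 had 18S signals of 11 and 7.93, against 6.22 in animal 8 and 6.11 to 6.30 in the corn oil controls. Without the 5 arrays with the highest 18S signal, which leaves animal 8 alone in this group, the count was 886, and with a clock gene index as a covariate it was 1691.

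N-(1-naphthyl)ethylenediamine was compared with the feed control as the first of the chemicals classed as negative. Dbp, a clock output transcription factor, rose 23.6-fold (log2 change 4.56 ± 1.31, SE, n = 3 per group; limma adjusted p = 0.0142), from 5.22 in feed controls to 9.93, and Ppp1r3g, a glycogen-targeting phosphatase subunit, rose by 3.48 ± 0.669 (adjusted p = 0.00186). The core clock genes Arntl and Npas2 fell by 1.86 ± 0.406 and 1.80 ± 0.348, whereas Per1 and Per3 rose by 1.42 ± 0.284 and 1.20 ± 0.289. The mean of Npas2 went from 4.74 to 3.09, under the lowest array median, so the bound on its fall is the difference between those means. Arntl did not pass without probe sets of shared sequence (log2 change -0.39). Ppargc1a, a coactivator of gluconeogenesis and mitochondrial genes, rose by 1.68 ± 0.357, and Nipal1 and Cyp1a2 by 1.64 ± 0.168 and 1.26 ± 0.126. Nipal1 was also higher by 1.53 ± 0.168 in the corn oil control, without a chemical, than in the same feed control. Falls included Slco1a1 at -3.15 ± 0.59, Serpina12 at -3.10 ± 0.377 (adjusted p = 0.000218) and Hsd3b5 at -2.36 ± 0.444. The mean of Hsd3b5 went from 6.10 in feed controls to 3.90, under the lowest array median, so the bound on its fall is the difference between those means.

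Few lists passed with N-(1-naphthyl)ethylenediamine. Among 13 male-biased liver genes 4 fell and 2 rose, or 6 and 2 adjusted over the list alone, with Cyp7b1, an oxysterol hydroxylase, at -1.06 ± 0.182 beside Slco1a1 and Hsd3b5 (camera adjusted p = 0.00279; adjusted p = 0.548 with an estimated correlation). The male-biased list was also called lower in the corn oil control, without a chemical, against the same feed control, as given below. Stellate cell and matrix genes had a median of -0.34, with 2 of 17 lower and 0 adjusted over the list alone (camera adjusted p = 0.00535; adjusted p = 0.547 with an estimated correlation). Circadian clock genes changed in both directions, 8 up and 3 down of 17, also adjusted over the list alone, and did not pass as a list that moves one way (camera adjusted p = 0.828). NRF2 targets rose in 11 of 26 cases and fell in 1, or 13 and 1 adjusted over the list alone, and that list did not pass either (camera adjusted p = 0.463). The metallothionein genes Mt1 and Mt2 were called at 1.74 ± 0.518 and 2.38 ± 0.68. Both calls were lost without treated animal 12 (adjusted p up to 0.0639 for Mt1 and 0.064 for Mt2), that of Mt1 also without feed control 27 or 29 and that of Mt2 also without treated animal 15.

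For N-(1-naphthyl)ethylenediamine 3536 genes passed, 3004 higher and 532 lower, against 966 and 791 after quantile normalization and 668 and 1836 with arrays centred on the median of the tested genes. This group had the lowest mean RNA integrity number, a beta-actin 3' minus 5' difference of 1.60 ± 0.215 (SD, n = 3) against 0.943 ± 0.0485 in feed controls, and 18S signals of 11.6, 10.3 and 6.97. The count was 352 with the integrity number as a covariate, 44 with the beta-actin difference as a covariate, 1759 with the clock gene index and 529 without the 5 arrays with the highest 18S signal, which leaves animal 15 alone in this group. It was 1839 without treated animal 12 and 2055 without feed control 29.

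**Figure D3:**
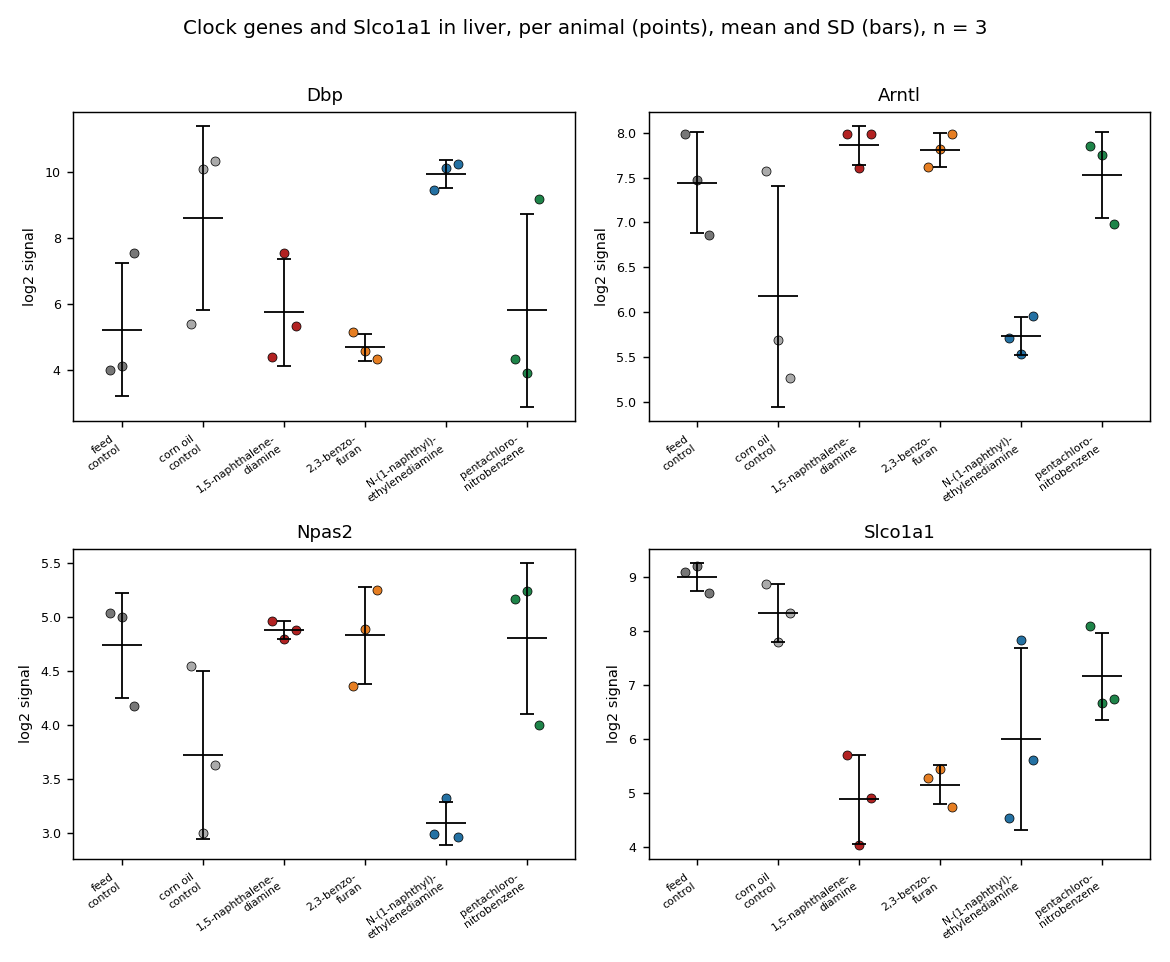
Log2 signal of the clock genes Dbp, Arntl and Npas2 and of Slco1a1 on the vertical axes in the 6 groups; points are animals, horizontal bars are means and error bars are SD (n = 3). Mean Dbp signal was 5.22 in feed controls, 8.61 in corn oil controls and 9.93 with N-(1-naphthyl)ethylenediamine.

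Clock genes also varied among animals that received no chemical. Dbp lay at 4.00, 4.11 and 7.53 in the feed controls and at 5.40, 10.1 and 10.3 in the corn oil controls. With N-(1-naphthyl)ethylenediamine it lay at 9.46, 10.1 and 10.2. In 2,3-benzofuran Dbp was lower than in its control by 4.03 ± 1.31 on the log2 scale (limma adjusted p = 0.0295), a call that was lost without treated animal 6, 8 or 10 or corn oil control 24 or 25 (adjusted p up to 0.127). The clock index, the mean of Dbp, Tef, Per3 and Nr1d2 minus that of Arntl, Npas2, Cry1 and Nfil3, lay between 3.31 and 3.87 with N-(1-naphthyl)ethylenediamine and between -0.88 and 3.90 in the 6 controls. The time of day at which tissue was taken is not given in the sources used here.

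Pentachloronitrobenzene, the other chemical classed as negative, was compared with the same feed control. Interferon-induced genes made up much of the top of this comparison. Ifit1 rose 7.94-fold (log2 change 2.99 ± 0.314, SE, n = 3 per group; limma adjusted p = 1.14e-05), Usp18, which removes the ubiquitin-like protein ISG15, by 2.38 ± 0.21, Gbp6 by 2.04 ± 0.286, Oasl1 by 1.96 ± 0.187 and Oas1a by 1.93 ± 0.161. Of 20 interferon response genes 16 rose, and 18 adjusted over the list alone, with Gbp3 at 1.77 ± 0.149 (camera adjusted p = 7.8e-17; adjusted p = 0.0798 with an estimated correlation). Macrophage and lymphocyte marker lists did not pass in this comparison (camera adjusted p = 0.66 and 0.993), with 1 of 20 and 2 of 12 members called higher, also adjusted over the list alone. These were Mpeg1 at 0.52 ± 0.133, Coro1a at 0.54 ± 0.161 and Ighm at 0.53 ± 0.22. The call of Coro1a was lost without feed control 29 (adjusted p = 0.0631), that of Ighm without feed control 29 or any 1 treated animal (adjusted p up to 0.195), and Ighm turned to -0.94 without probe sets of shared sequence (adjusted p = 0.0166). The largest falls that held without any 1 array were in Csdc2 at -1.89 ± 0.245 and Pik3cd at -1.66 ± 0.295.

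Cholesterol synthesis genes rose in 16 of 20 cases with pentachloronitrobenzene, and in 19 adjusted over the list alone, with Sqle at 1.63 ± 0.216, Cyp51 at 1.27 ± 0.156 and Nsdhl at 0.91 ± 0.121 (camera adjusted p = 1e-09; adjusted p = 0.197 with an estimated correlation). NRF2 targets rose in 17 of 26 cases and fell in 1, or 18 and 1 adjusted over the list alone, with Gstm3 at 1.83 ± 0.255, Gstm1 at 0.65 ± 0.0971 and Gstp1 at 0.58 ± 0.0852 (camera adjusted p = 4.1e-07; adjusted p = 0.288 with an estimated correlation). Glutathione S-transferases rose in 11 of 19 cases, and in 12 adjusted over the list alone (camera adjusted p = 1.06e-05; adjusted p = 0.452 with an estimated correlation). The interferon response, cholesterol synthesis and glutathione S-transferase lists were also called higher in the corn oil control. That control had no chemical and was set against the same feed control, as given below. Targets of the xenobiotic receptors CAR and PXR rose in 10 of 20 cases, and in 11 adjusted over the list alone, with Aldh1a7 at 0.67 ± 0.0866 and Abcc3 at 0.64 ± 0.104 (camera adjusted p = 0.00472; adjusted p = 0.452 with an estimated correlation), a call that was lost without feed control 28 (adjusted p = 0.0906). Cell cycle genes lay lower, with Ccne1 at -0.95 ± 0.123, 2 of 20 falling and 18 not passing, also adjusted over the list alone (camera adjusted p = 0.00316; adjusted p = 0.136 with an estimated correlation). Cyp3a16, a female-biased cytochrome P450, was called at 3.22 ± 0.758 (adjusted p = 0.00949), but not without feed control 29 (adjusted p = 0.063).

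In this comparison 2249 genes passed, 1778 higher and 471 lower, against 366 and 526 after quantile normalization and 312 and 1627 with arrays centred on the median of the tested genes. RNA integrity numbers (8.53 ± 0.231, SD, n = 3) and 18S signals (6.23 ± 0.0457) lay close to those of the feed controls (8.9 ± 0.173 and 6.39 ± 0.242). The count was 656 without feed control 29, 660 without treated animal 16 and 881 without treated animal 18, and 400 when the 6 arrays compared were fitted alone.

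**Figure D4:**
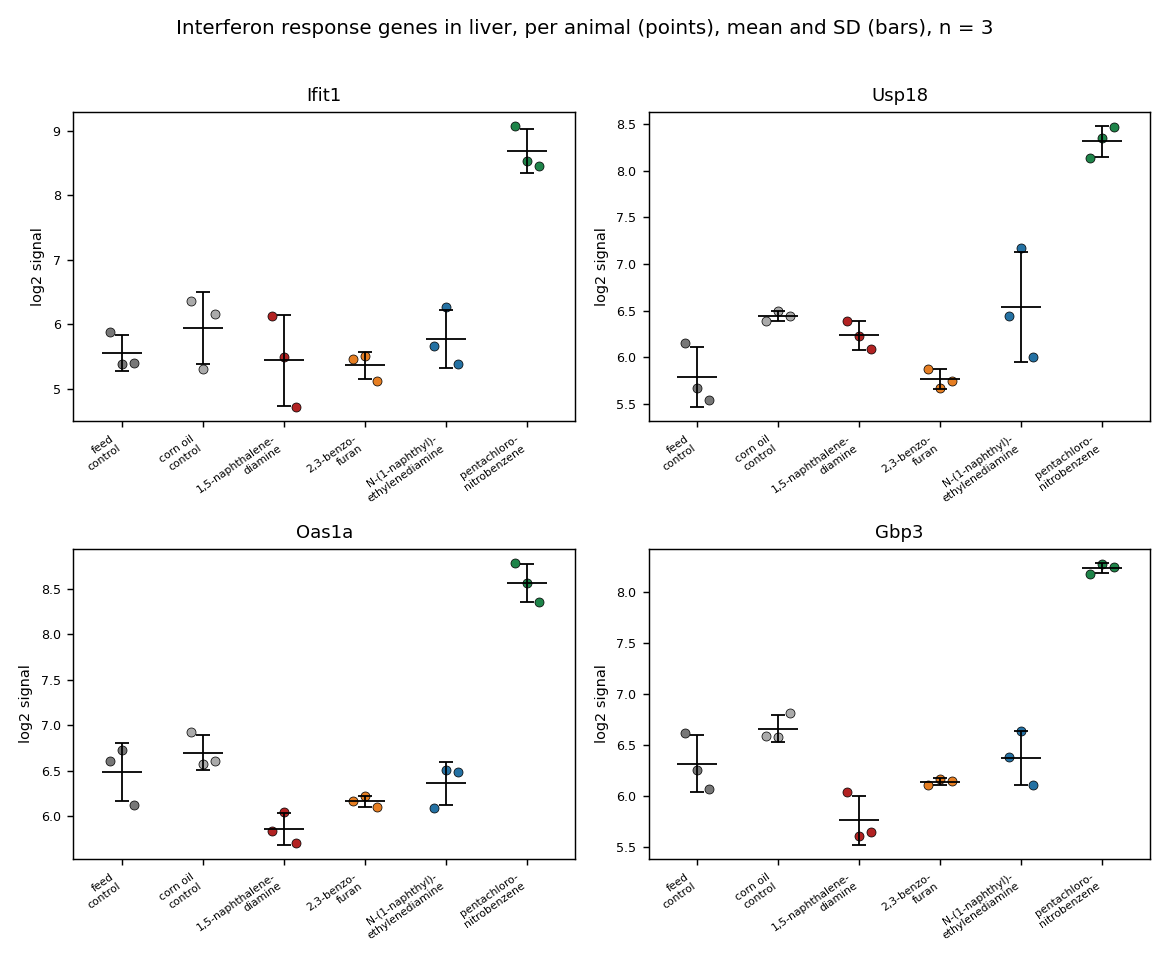
Log2 signal of Ifit1, Usp18, Oas1a and Gbp3 on the vertical axes in the 6 groups; points are animals, horizontal bars are means and error bars are SD (n = 3). Mean Ifit1 signal was 8.69 with pentachloronitrobenzene and 5.55 in feed controls.

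The control groups were compared with each other to see what gavage with corn oil differed by without a chemical. Nipal1, a magnesium transporter family gene, was 2.88-fold higher in the corn oil control (log2 difference 1.53 ± 0.168, SE, n = 3 per group; limma adjusted p = 0.000452), and Bid, an apoptosis regulator, was higher by 1.07 ± 0.126. Cholesterol synthesis genes were higher as a group, 5 of 20, or 14 adjusted over the list alone, with Nsdhl at 0.81 ± 0.121, Fdps at 0.94 ± 0.157 and Sqle at 1.16 ± 0.216 (camera adjusted p = 6.12e-20; adjusted p = 0.107 with an estimated correlation). Without feed control 28 these 3 calls were lost (adjusted p up to 0.0893 for Nsdhl, 0.121 for Fdps and 0.26 for Sqle), those of Fdps and Sqle also without corn oil control 22, 24 or 25, and after quantile normalization 0 of the 20 passed in limma. Fatty acid synthesis genes lay higher with a median of 0.394, with Acly at 0.73 ± 0.181 (adjusted p = 0.131), and 9 of 18 were higher only when adjusted over the list alone (camera adjusted p = 4.73e-10; adjusted p = 0.107 with an estimated correlation). Interferon response genes lay higher with a median of 0.324, with Usp18 at 0.66 ± 0.21 (adjusted p = 0.284), and 0 of 20 passed in limma, 5 when adjusted over the list alone and 7 at an unadjusted p under 0.05 (camera adjusted p = 6.63e-06; adjusted p = 0.339 with an estimated correlation). Macrophage and Kupffer cell markers were also called higher as a list, with 0 of 20 passing in limma and 2 higher at an unadjusted p under 0.05. That call was lost without any 1 of 4 of the 6 arrays (camera adjusted p up to 0.325). Glutathione S-transferases were called higher too, with Gstm2 at 0.75 ± 0.105 (limma adjusted p = 0.0045), and held without any 1 array (camera adjusted p up to 0.0101). The aryl hydrocarbon receptor and cell cycle lists were called higher with 0 members passing in limma. Leaving out any 1 of 4 of the 6 arrays ended each call (camera adjusted p up to 0.267 and 0.227). Female-biased genes had a median of 0.889, with 1 of 12 passing and 5 adjusted over the list alone (camera adjusted p = 5.63e-07; adjusted p = 0.174 with an estimated correlation). Male-biased genes lay lower in the corn oil control, with 0 of 13 passing in limma and 4 lower at an unadjusted p under 0.05. Hsd3b5 was at -1.57 ± 0.444 (limma adjusted p = 0.208) and Elovl3 at -1.67 ± 0.37 (limma adjusted p = 0.0922). That list call held without any 1 array (camera adjusted p up to 0.00486).

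In limma 15 genes differed between the controls, each of them higher with corn oil, and 1152 had an unadjusted p under 0.05. After quantile normalization the count was 8, and 6 with the 6 arrays fitted alone. Leaving out 1 array gave 83 without feed control 27, 3 without feed control 28, 23 without corn oil control 22, 5 without corn oil control 24 and 4 without corn oil control 25.

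1,5-Naphthalenediamine and N-(1-naphthyl)ethylenediamine are both naphthylamines given at 2000 ppm in feed, so they were also compared directly. The former carries an amino group at positions 1 and 5 of the naphthalene ring and the latter an ethylenediamine chain at position 1. Equal doses by weight are not equal molar doses. Cyp1a1 was at least 8.38-fold higher with 1,5-naphthalenediamine (log2 difference 3.07 ± 0.291, SE, n = 3 per group; limma adjusted p = 3.96e-06), Abcc4 was higher by 2.69 ± 0.287, Gstm3 by 2.31 ± 0.255 and Aox1, aldehyde oxidase, by 2.17 ± 0.128. Of 26 NRF2 targets 20 were higher, and 22 adjusted over the list alone, with Ugdh at 2.13 ± 0.143 and Gstp1 at 1.04 ± 0.0852 (camera adjusted p = 3.42e-28; adjusted p = 0.0281 with an estimated correlation). Glutathione S-transferases were higher in 10 of 19 cases, and in 14 adjusted over the list alone, with Gstm2 at 1.71 ± 0.105 (camera adjusted p = 5.55e-16; adjusted p = 0.151 with an estimated correlation). Cdkn1a, the p53 target that encodes p21, was higher by 2.52 ± 0.53 (adjusted p = 0.00854), a call that was lost without N-(1-naphthyl)ethylenediamine animal 14 (adjusted p = 0.0546). With it 4 of 18 p53 targets were higher, 5 adjusted over the list alone (camera adjusted p = 0.00184; adjusted p = 0.339 with an estimated correlation). Of 31 lists 6 were called higher and 5 lower with 1,5-naphthalenediamine. Endothelial markers were among the lower, with 3 of 15 lower at an unadjusted p under 0.05. Txnip, a thioredoxin-binding protein gene, was lower with 1,5-naphthalenediamine by 1.75 ± 0.23 on the log2 scale, Mmd2 by 1.58 ± 0.244 and Lepr, the leptin receptor, by 1.49 ± 0.264.

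Among the 26 genes with the largest rises or falls under either compound, 14 differed and 12 did not pass. The difference in Slco1a1 was -1.11 (95% interval -2.35 to 0.13), in Serpina12 0.65 (-0.14 to 1.44), in Csdc2 0.10 (-0.42 to 0.61) and in Pik3cd 0.19 (-0.43 to 0.81), all in log2 units. Hsd3b5 lay near background with both compounds, so its difference was not measurable. Dbp and Rgs16 did not pass either, but their intervals exclude 0, with differences of -4.18 (-6.93 to -1.43, limma adjusted p = 0.0692) and -2.30 (-3.77 to -0.84, limma adjusted p = 0.0605). In all 666 genes differed, 427 higher and 239 lower with 1,5-naphthalenediamine, against 458 and 414 after quantile normalization and 447 of 839 higher with arrays centred on the median of the tested genes. The count was 93 with the RNA integrity number as a covariate, 124 with the clock index and 99 without the 5 arrays with the highest 18S signal, and 313, 349, 359 and 425 without 1,5-naphthalenediamine animal 5, N-(1-naphthyl)ethylenediamine animals 15 and 14, and 1,5-naphthalenediamine animal 2.

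The last contrast set the mean effect of the chemicals classed as liver carcinogens against the mean effect of those classed as negative. Its p-values, here and below, measure the spread between animals and not between chemicals, so they do not show that the classes differ in general. Tfrc was higher in the carcinogen effect by 2.25 ± 0.284 on the log2 scale (SE, 6 treated arrays per class) and Aox1 by 1.92 ± 0.111. Snhg11, Abcc4 and Cbr3 were higher as well (limma adjusted p = 4.06e-07 for Snhg11), but lay below the array medians in both controls, so no size is given for them. NRF2 targets were higher in 21 of 26 cases, and in 22 adjusted over the list alone (camera adjusted p = 1.55e-30; adjusted p = 0.0103 with an estimated correlation). The median change of that list was 1.03 with 1,5-naphthalenediamine, 1.19 with 2,3-benzofuran, 0.138 with N-(1-naphthyl)ethylenediamine and 0.444 with pentachloronitrobenzene. Interferon response genes were lower in 15 of 20 cases, and in 20 adjusted over the list alone, with Oas1a at -1.56 ± 0.139, Gbp3 at -1.52 ± 0.129 and Ifit3 at -1.38 ± 0.136 (camera adjusted p = 2.77e-27; adjusted p = 0.0103 with an estimated correlation). Its median change was -0.295, -0.539, 0.00302 and 1.12 in the same order, and 0.324 in the corn oil against the feed control. Noct, a circadian deadenylase-family gene, was lower by 1.85 ± 0.298 and the transporter gene Slc22a7 by 1.36 ± 0.195. In every array of both carcinogens the genes named in this paragraph lay on one side of every array of both other chemicals, after subtraction of the control means. For the largest changes this was a condition for being named.

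Female-biased liver genes were lower in the carcinogen effect in 7 of 12 cases, or 8 adjusted over the list alone, with Hao2 at -2.41 ± 0.413 (camera adjusted p = 1.41e-07; adjusted p = 0.138 with an estimated correlation). With 1,5-naphthalenediamine against its control this list did not pass. Its members with the largest t statistics there, Nipal1, Fmo2 and Cyp2b13, rose by 1.12 ± 0.168, 0.86 ± 0.211 and 0.84 ± 0.232. In the corn oil against the same feed control Nipal1 was higher by 1.53 ± 0.168, and Fmo2 was at 0.97 ± 0.211 (limma adjusted p = 0.0902). The fall with 2,3-benzofuran was measured against a corn oil control in which the list lay higher than in the feed control, as given above. Male-biased genes were higher in 6 of 13 cases and lower in 1, or 6 and 2 adjusted over the list alone, with Cyp2d9 at 1.96 ± 0.197 (camera adjusted p = 0.000261; adjusted p = 0.321 with an estimated correlation). Against its own control neither carcinogen had this list called. The effect of 2,3-benzofuran was measured against a corn oil control in which the list lay lower than in the feed control. With 1,5-naphthalenediamine Cyp2d9 rose by 1.33 ± 0.228, whereas Slco1a1 and Hsd3b5 fell, as given above. Arrays of the classes overlapped for Hao2 and Cyp4a12a, and the change of Cyp4a12a was at least 4.48 with 2,3-benzofuran. Acute phase genes were lower in 7 of 24 cases and higher in 1, or 15 and 1 adjusted over the list alone, with Lbp at -0.82 ± 0.116 (camera adjusted p = 1.86e-07; adjusted p = 0.321 with an estimated correlation). Macrophage and Kupffer cell markers were lower in 6 of 20 cases and higher in 1, or 13 and 1 adjusted over the list alone, with Mpeg1 at -0.97 ± 0.115 (camera adjusted p = 8.33e-07; adjusted p = 0.321 with an estimated correlation). Over all contrasts and lists, 3 of 84 camera calls hold with an estimated correlation: NRF2 targets between the naphthylamines and between the classes, and the interferon response between the classes.

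In this contrast 876 genes passed, 463 higher and 413 lower, and 1348 passed without feed control 29. Pairing the chemicals in the other possible ways gave 332 genes for 1,5-naphthalenediamine with N-(1-naphthyl)ethylenediamine and 111 for 1,5-naphthalenediamine with pentachloronitrobenzene. Each class holds 2 chemicals, and the count was 149 with the RNA integrity number as a covariate, 246 with the clock index and 259 without the 5 arrays with the highest 18S signal.

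The calls of the chemicals overlapped. 1,5-Naphthalenediamine and 2,3-benzofuran, which have separate controls, shared 2109 genes that rose and 465 that fell, where independent lists give 949.8 and 77.59, and 22 genes went opposite ways. After quantile normalization they shared 701 and 702, where independent lists give 187.3 and 158.5. The feed chemicals share their 3 controls. 1,5-Naphthalenediamine and N-(1-naphthyl)ethylenediamine shared 2076 rises and 379 falls, where independent lists give 946.9 and 44.72. Simulated unchanged groups that share a control group give 1654 and 171 on average and at most 2333 and 374. The pair of 1,5-naphthalenediamine and pentachloronitrobenzene shared 1477 and 392, against 560.5 and 39.6 for independent lists and 1079 and 155 on average, at most 1530 and 341, in the simulation. For N-(1-naphthyl)ethylenediamine and pentachloronitrobenzene the shared counts were 1058 and 276, against 438.9 and 20.59 for independent lists and 921 and 99, at most 1409 and 262, in the simulation. In these 3 pairs the shared rises lay within the range of the simulation and the shared falls above it. The simulated control group was drawn from residuals of all arrays and not from the 3 feed controls. It therefore does not show what these particular controls would give. With the second chemical set against the corn oil controls instead, which differ in vehicle and route, 1,5-naphthalenediamine shared 919 rises and 158 falls with N-(1-naphthyl)ethylenediamine, where independent lists give 431.5 and 23.79. With pentachloronitrobenzene it shared 191 and 59, where independent lists give 85.43 and 7.062. Part of the excess in the feed pairs may come from the shared controls.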

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

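The tests on the added bacterial transcripts, on feed control 29, on the range of Dbp, on the clock index of the treated animals and on the beta-actin covariate were chosen only after the results were seen. The splits of the arrays and the bound for the clock covariate were planned before theirs.

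The 3 probe sets for 18S ribosomal RNA, which no comparison used, gave more signal on 6 treated arrays than on any control array, where the highest mean was 6.67. The values were 11.6, 10.3 and 6.97 for N-(1-naphthyl)ethylenediamine animals 14, 12 and 15, 11 and 7.93 for 2,3-benzofuran animals 6 and 10, and 9.97 for 1,5-naphthalenediamine animal 4.

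More genes were higher than lower with each of the 4 chemicals against its control. Bacterial transcripts added before hybridization were also higher on the 12 treated than on the 6 control arrays, by a median of 0.217 log2 (18 of 18 probe sets, exact permutation p = 0.000862 over 18564 regroupings), so lower signal on the control arrays may account for much of the excess. Greater RNA output in treated livers cannot be judged from these transcripts. Each sample was labelled from 10 ug of RNA and the transcripts were added only before hybridization, so a greater output would not show. The change of genes exceeded that of added transcripts of the same level by at most 0.00151 log2 over the 4 chemicals (median over probe sets matched in level). The mean over 4 transcripts was at most 0.0104 (SE 0.0143), and the difference of medians without matching at most 0.0583. Feed control 29 alone does not account for the excess of higher genes, since the median change without it was 0.0856 or more in each of the 3 feed chemicals. How the authors normalized the arrays, which is not given in the sources used here, stays open.

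Clock genes differed both between and within groups. Dbp differed by 4.93 log2 among the 3 corn oil controls and by 3.53 among the feed controls, which no chemical can account for, so the time of day at which tissue was taken may be a source of the differences. For an effect of N-(1-naphthyl)ethylenediamine on the clock, 0 of its 3 animals had a clock index outside the range of the 6 controls. That range is wide, the times are not given in the sources used here, and the 2 explanations cannot be told apart for this group.

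The genes called for N-(1-naphthyl)ethylenediamine came from the group with the lowest mean RNA integrity number. With the beta-actin 3' minus 5' signal as a covariate the changes of these genes kept a slope of 0.755 on the unadjusted ones (0.719 to 0.799 leaving out 1 array), the median size of change went from 0.456 to 0.349 and its median standard error from 0.123 to 0.165, and 44 genes passed. With the clock index the slope was 0.856 (0.789 to 0.911), the median size 0.444 and the standard error 0.162, and 1759 passed. For clock phase the slope lies above the 0.5 set beforehand for a cause, but its lowest value is under the bound of 0.8 set against one. Calls were lost with the clock index mainly through a larger error. That index also goes with this group, at 3.31 to 3.87 against -0.88 to 1.55 in the feed controls. The test therefore cannot decide on clock phase. Calls ended through a smaller change and a larger error with the beta-actin signal, whose slope also lies above 0.5, and because that signal goes with this group its part cannot be told apart from that of the chemical.

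Other splits of the same arrays were counted for each contrast. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and in each contrast 1 split, the real one, reached its count. The real counts and the highest of the other splits were 4859 and 0 for 1,5-naphthalenediamine, 3936 and 2 for 2,3-benzofuran, 3536 and 1 for N-(1-naphthyl)ethylenediamine, 2249 and 2 for pentachloronitrobenzene, 15 and 14 for the controls, and 666 and 0 between the naphthylamines. For the carcinogens against the other chemicals, with control means subtracted and without a mean-variance trend, the real split gave 926 genes and the highest of the others 2, and 1 of 100 splits drawn from 462 was as large. These splits break up the 3 arrays of each chemical, so they say nothing of the classes. By whole chemicals there are 3 pairings, too few for a share under 0.05, and the others gave 332 and 111 genes, against 876, in the model of all arrays.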

How the results depend on the processing

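Alternatives chosen only after the data were seen were the beta-actin and clock index covariates, leaving out the 5 arrays with high 18S signal, centring on the tested genes, corn oil controls for a second feed chemical, and alias matching. Counts are given in the order 1,5-naphthalenediamine, 2,3-benzofuran, N-(1-naphthyl)ethylenediamine, pentachloronitrobenzene, controls, naphthylamines, carcinogens against others, where all 7 are named, and only those that moved by over 1.5 times are given. At least a 2-fold change left 202, 214, 128, 92, 4, 93 and 96 genes, and an adjusted p under 0.01 left 2587, 2030, 1373, 435, 5, 241 and 428, by construction. Quantile normalization gave 2961 for 1,5-naphthalenediamine, 1757 for N-(1-naphthyl)ethylenediamine, 892 for pentachloronitrobenzene and 8 for the controls. Fits of only the groups compared, with fewer arrays, gave 2752, 1490, 400 and 6 for the same contrasts. Array weights gave 2224 for N-(1-naphthyl)ethylenediamine and 1447 for the carcinogens against others. The RNA integrity number gave 352 for N-(1-naphthyl)ethylenediamine, 93 between the naphthylamines and 149 for the carcinogens against others, and the beta-actin covariate 44 for N-(1-naphthyl)ethylenediamine. The clock index gave 1691 for 2,3-benzofuran, 1759 for N-(1-naphthyl)ethylenediamine, 7 for the controls, 124 between the naphthylamines and 246 for the carcinogens against others. Without the 5 arrays with high 18S signal counts were 2772, 886, 529 for the first 3 chemicals, 4 for the controls, 99 between the naphthylamines and 259 for the carcinogens against others, with the lone array of 2,3-benzofuran and of N-(1-naphthyl)ethylenediamine assumed to vary like the other groups. Centring on the tested genes gave 8 for the controls. Apart from fewer arrays and stricter thresholds, the cause was not tested.

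Leaving out 1 array gave 3306 to 4970 genes for 1,5-naphthalenediamine, 2798 to 3282 for 2,3-benzofuran, 1839 to 3689 for N-(1-naphthyl)ethylenediamine, 656 (without feed control 29) to 2505 for pentachloronitrobenzene, 3 to 83 for the controls, 313 to 550 between the naphthylamines and 656 (without corn oil control 24) to 1348 for the carcinogens against others. Dbp turned with the clock index as a covariate, of which it is a part, to 0.3449 in 2,3-benzofuran (adjusted p = 0.523 in limma) and -0.2641 in N-(1-naphthyl)ethylenediamine (0.613). The acute phase list, not called between the controls, was called higher without feed control 28 (camera adjusted p = 0.0394); leaving out 1 array took its signed minus log10 adjusted p from -0.9042 (without feed control 27) to 1.404, and the cause was not tested.

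Among genes of lists that did not pass, those with a change of sign were, without probe sets of shared sequence, Ighm in pentachloronitrobenzene (-0.94) and Uroc1 (-0.71) and Sdha (-0.082) in N-(1-naphthyl)ethylenediamine, and, with the mean of all probe sets, Tap1 (-0.042) and Uroc1 (-0.097) in the latter. Uroc1 was also at -0.089 there without the 5 arrays. Centring on the tested genes turned Apoa2 (-0.041) and Apoc3 (-0.11) in 1,5-naphthalenediamine, Apoc3 in 2,3-benzofuran (-0.015) and pentachloronitrobenzene (-0.021), and Ahsg (-0.027), Apoa2 (-0.10) and Rbp4 (-0.064) in N-(1-naphthyl)ethylenediamine. The cause was not tested.

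Of 680 results of named genes, 579 were on the same side of the threshold in the same direction after quantile normalization, 497 with the RNA integrity number, 570 with the beta-actin covariate, 514 with the clock index and 439 without the 5 arrays. Of 84 list calls, 72 held after quantile normalization, 41 with fry, 73 with the RNA integrity number, 65 with the clock index and 3 with an estimated correlation. Arntl in N-(1-naphthyl)ethylenediamine was -0.39 without probe sets of shared sequence and did not pass (adjusted p = 0.102 in limma). With alias matching of listed symbols, which first put H19, Reg1, Trf and Rpl23 at other genes, 89 of 224 list tests were called, against 84 of 217. Ribosomal proteins were then called in 1,5-naphthalenediamine (camera adjusted p = 0.0424, now 0.0763) and N-(1-naphthyl)ethylenediamine (0.0222, now 0.0542), fetal genes were not called in 2,3-benzofuran (0.0534, now 0.013), and a pancreas list, now too short to test, was called lower in the 4 chemicals (0.00131, 0.0184, 0.0137 and 0.00877). The 4th list concerned, hepatocyte secreted proteins, had the same calls both ways. Pseudocount alternatives were not run, because the values are already log2. No paired analysis was possible because animal numbers are unique to each array. Signal over background limits dim genes: without the filter 67 of 84 list calls held and 19 were gained.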

Other observations

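The contrast and the lists in this part were planned, and no test here was chosen after its result was seen. Asns, asparagine synthetase, and Hspb1, a small heat shock protein, were 3.49-fold and 4.48-fold higher in the effect of the carcinogens than in that of the other chemicals (log2 SE 0.137 and 0.175, 6 treated arrays per class; limma adjusted p = 1.72e-07 and 3.98e-07), although arrays of the classes overlapped for both. These differences came from 2,3-benzofuran: Asns changed by 3.21 and Hspb1 by 3.20 with it, and with 1,5-naphthalenediamine the values were -0.29 and 0.27 (limma adjusted p = 0.561 and 0.0883). The endoplasmic reticulum stress list was higher in this contrast with 2 of 19 genes passing, or 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0085; adjusted p = 0.343 with an estimated correlation). Against their own controls the same list was lower with 1,5-naphthalenediamine (camera adjusted p = 0.0124; adjusted p = 0.552 with an estimated correlation), N-(1-naphthyl)ethylenediamine (0.00279; 0.548) and pentachloronitrobenzene (0.00472; 0.491), and did not pass with 2,3-benzofuran (0.517), where its median was 0.189. It was also lower in the corn oil than in the feed control, with 0 of 19 genes passing in limma, also adjusted over the list alone, and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0177; adjusted p = 0.587 with an estimated correlation), a call that was lost without feed control 28 or corn oil control 24 or 25 (adjusted p up to 0.394). Without feed control 28 the 3 lower calls of the chemicals were lost (adjusted p up to 0.107, 0.0705 and 0.119), the first also without 1,5-naphthalenediamine animal 4. With pentachloronitrobenzene 0 of 19 members passed in limma, and 2 were higher and 2 lower at an unadjusted p under 0.05. The members with the largest t statistics with 1,5-naphthalenediamine went both ways. Ddit3 was called higher at 0.295 ± 0.106, and Pdia6 and Dnajc3 lower at -0.565 ± 0.135 and -0.601 ± 0.163. The heat shock list, with 3 of 11 higher and 1 lower, did not pass (camera adjusted p = 0.149).

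Poly-A control transcripts had a mean of 3.49 on the array of 1,5-naphthalenediamine animal 2 and of 6.86 to 8.20 on the other arrays. Feed control 29 had the lowest array weight, 0.258. Xist probe set signals of 6.38 to 11.5 and Y-linked signals of at most 3.54 were measured over all 18 arrays, and the labels give all animals as female.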
